A study of Bos taurus with 12 samples.

How the data were processed

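Total RNA from bone-marrow mesenchymal stem cells of 3 juvenile cattle donors, each under 4 preconditioning conditions, was hybridised to 12 bovine whole-transcript Affymetrix arrays. The donor and the condition of each array were taken from its title. Per the labels, expression was normalised by robust multi-array averaging (RMA), and the submitters' processing notes name Partek 6.6. The range of the deposited values is that of log2 signals, and they were taken as such. The submitters' design text also mentions an adjustment for the false discovery rate. The statistical test, any donor term, filters and the library version are not given in the sources used here. The table held 26773 probe sets with a value on every array, and no value column was without a sample. Array medians lay between 6.59 and 6.66, so the values were used as deposited.

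Gene names came from the platform's annotation table, with 93 symbols updated through their Entrez identifiers to those of a RefSeq gene table for the assembly ARS-UCD2.0, of which no coordinates were used. A single symbol was available for 18550 probe sets, several for 595, and 7628 are unnamed here. No gene was named from a probe set with several symbols. A gene with several probe sets, as held for 416 symbols, was represented by the one with the highest mean, which gave 18087 symbols. The probe set of ACTA2, fixed as a check gene, was annotated to several genes, so it is not reported.

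The design, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a constant prior variance) on all 12 arrays with group as the only term, so that the 4 groups shared 1 estimate of the spread (8 residual and 3.14 prior degrees of freedom). P-values were adjusted by Benjamini and Hochberg over all probe sets of a comparison, with a threshold of 0.05. The 8 comparisons were TGF-β3 at each oxygen tension, hypoxia without and with TGF-β3, both against neither, the interaction, and each factor averaged over the other. Correlations of effects between comparisons are across probe sets, and 3 pairs of effects were compared. Both against neither shares its control arrays with TGF-β3 at 21% and with hypoxia without TGF-β3, and no correlation or overlap with these was computed.

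The 24 gene lists, which hold 474 measured genes of 515 written, covered TGF-β response, BMP response, glycolysis, hypoxia response outside glycolysis, oxidative phosphorylation, cartilage, chondrocyte hypertrophy and bone, adipogenic, contractile, fibrous matrix, collagen modification and crosslinking, matrix proteases and inhibitors, cell cycle, mesenchymal stromal, inflammatory, interferon response, unfolded protein and amino acid stress, sterol synthesis and Wnt response genes, and markers of haematopoietic, endothelial, erythroid, osteoclast, and muscle or neural cells. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without comparing them with other genes. The direction given by camera, the median and the mean had the same sign for every list that camera called. Members were also adjusted over the list alone. The members given as examples of a list that were not called over all probe sets were chosen after their values were seen.

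Genes were named by a fixed rule. For each single comparison the rule took the 8 largest rises and 8 largest falls among called probe sets with 1 symbol and the same direction in 3 donors, up to 4 called members of each list, and fixed check genes (SMAD7, TGFBI, VEGFA, PDK1, NDRG1, SOX9, ACAN and COL2A1). For the others it took 5 each way, and where nothing was called the 3 with the smallest p each way. RAB3C had a second probe set with a change in the other direction that was not called (-0.32 for the interaction).

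Donor numbers in the titles mark cells of the same animal, so arrays with the same number are paired. Deviations from the group means correlated with r between 0.177 and 0.602 for the 18 pairs of arrays from 1 donor in different conditions, and between -0.44 and 0.1 for the 36 pairs of different donors and conditions. All 12 arrays correlated best with their own donor. A fit with donor as a fixed block (6 residual degrees of freedom) was therefore run beside the one without, and its value is given where it changes a call or moves a count given here by over 1.5 times.

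Further alternatives were a random donor block, equal array medians, quantile normalisation, leaving out probe sets below the median signal, an intensity trend, no variance moderation, only the 2 groups compared, 1 probe set per symbol, a 2-fold threshold, and leaving out each array and each donor. Camera with an estimated correlation together with the donor block, the 2-fold threshold with the donor block, and the alternatives for list examples, were added after seeing the data.

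The tests were checked on simulated data of 26773 probe sets with the real spread, in 5 runs with 200 changed probe sets each. For TGF-β3 at atmospheric oxygen, changes of 0.5, 1 and 2 in log2 were found in 20.6%, 80% and 96.4% of cases, and 1.5% of calls were false. With the donor block 34.0%, 84.5% and 97.0% were found, and 4.91% of calls were false. For TGF-β3 averaged over oxygen the shares found were 53.4%, 91.3% and 99.4%, and 1.57% of calls were false. The block found 69.0%, 93.7% and 99.4% there, and 5.31% of its calls were false. A list shifted by 0.3 was found in 5 of 5 runs. Apart from the donor differences, the spread was drawn independently for each probe set, so the runs do not check list calls against correlation between members. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No array was left out, and no genome coordinates were used.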

Results

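Genome-wide expression was measured on 12 arrays in mesenchymal stem cells from juvenile bovine bone marrow, multipotent stromal cells that can be turned towards cartilage, bone or fat. Cells from each of 3 donors were expanded for a week under 4 conditions, at atmospheric oxygen (21%) or in hypoxia (2%), without or with TGF-β3 at 10 ng/mL, a growth factor used to induce cartilage formation. Each condition thus held 3 arrays, 1 per donor. The log2 signal of 26773 probe sets was present on every array, and array medians lay between 6.59 and 6.66. The number of arrays limits the precision. Changes are given as log2 differences between group means ± the standard error from limma, with n = 3 per group, and adjusted p-values are those of limma over all probe sets unless stated otherwise. The comparisons address what the preconditioning with TGF-β3, with low oxygen and with both did to gene expression.

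The largest rise with TGF-β3 at atmospheric oxygen was that of ALDH1A1, a retinaldehyde dehydrogenase, which rose by 5.27 ± 0.64 (38.5-fold, adjusted p = 0.00162). PADI4, an enzyme that converts arginine in proteins to citrulline, rose by 4.61 ± 0.52 (24.5-fold, adjusted p = 0.00115). FGF18, a growth factor that acts on chondrocytes, rose by 2.62 ± 0.21 (adjusted p = 0.00015). ABI3BP, an extracellular matrix protein, fell by 5.69 ± 0.88 (adjusted p = 0.00635), and FABP4, a fatty acid carrier of adipocytes, fell by 4.57 ± 0.52 (adjusted p = 0.00116). The mean signal of FABP4 with TGF-β3 was 4.00, below the first quartile of every array (4.89 to 4.98), where signal above background was not tested. The mean of ABI3BP with TGF-β3 was 4.99, just above these quartiles, with 4.777, 4.657 and 5.543 in donors 1, 2 and 3. Among the other large rises were EMB at 3.72 ± 0.40, ATP6AP1L at 3.54 ± 0.37, the matrix protein gene DPT at 3.29 ± 0.48, PRR5L at 3.14 ± 0.25 and the prostaglandin E receptor gene PTGER3 at 3.14 ± 0.45. ITGBL1 (-2.84 ± 0.30), the vascular growth factor gene ANGPT2 (-2.78 ± 0.28), CYP1B1 (-2.77 ± 0.56), ULBP21 (-2.68 ± 0.40), PLS1 (-2.31 ± 0.37) and SVEP1 (-2.30 ± 0.24) had the next largest falls. In limma, 736 probe sets passed an adjusted p of 0.05, 342 higher and 394 lower, and 203 of them changed at least 2-fold (306 among the calls with donor as a block). Each of the 736 had the same direction in 3 of 3 donors, as did 40.2% of all probe sets. Passing the test with 3 arrays per group favours this, so it is no separate support. The count was 1701 with donor as a block, 29 without donor 2, 95 without donor 1 and 447 without donor 3. It was 282 or 289 without the untreated array of donor 2 or 3, and 399 or 390 without the treated array of donor 1 or 2. Of 48 named genes called here, 26 kept the call without any 1 array and 3 (PRR5L, FGF18 and PMEPA1) without any donor, while 30, 43 and 18 lost it without donors 1, 2 and 3. CYP1B1, LDLRAD4, BMP4, VEGFA, DES, TAGLN, COL14A1, COL8A1, PDGFRA, MX1 and FLT1 were among those that lost it on leaving out 5 of the 6 arrays in turn, and VLDLR, PLAUR and TIMP3 among those that did so with each of the 6.

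Known targets of TGF-β signalling rose as a group at atmospheric oxygen. Of 28 measured members of the TGF-β response list, 11 rose and 17 did not pass the test over all probe sets, while 18 rose and 3 fell adjusted over the list alone. The median change was 0.55 (limma camera, adjusted p = 2.09e-06, and adjusted p = 0.0293 with an estimated correlation). With the donor block as well the latter was 0.0818, so that the call was lost. The block gave 16 that rose and 2 that fell over all probe sets. PMEPA1, a TGF-β-induced inhibitor of SMAD signalling, rose by 1.93 ± 0.13, the SMAD corepressor gene SKIL by 1.24 ± 0.13, IL11 by 1.21 ± 0.20 and LDLRAD4 by 1.09 ± 0.25. SMAD7, the inhibitory SMAD fixed as a check of the treatment, changed by 0.67 ± 0.22 (adjusted p = 0.162, and 0.00515 with donor as a block, in a range of 0.00515 to 0.537 over all alternatives). TGFBI did not pass the test (0.70 ± 0.27, adjusted p = 0.241).

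Contractile genes rose as a group as well, with a median of 0.39 and 20 of 21 members above 0 (adjusted p = 3.55e-07, and adjusted p = 0.51 with an estimated correlation). The muscle intermediate filament gene DES rose by 2.21 ± 0.51 (adjusted p = 0.0435) and the actin-binding TAGLN by 0.55 ± 0.12 (adjusted p = 0.0329), and these were the 2 members called over all probe sets, against 11 with donor as a block. Adjusted over the list alone, 10 rose (17 rose and 1 fell with the block), among them CNN1 (1.44 ± 0.40) and MYOCD (0.84 ± 0.20), the transcriptional coactivator of smooth muscle genes. Over all probe sets these had adjusted p-values of 0.0883 and 0.0514, and 0.00137 and 0.00878 with donor as a block. The cell cycle list rose with a median of 0.22 and 27 of 28 members above 0 (adjusted p = 0.000484, and adjusted p = 0.616 with an estimated correlation), although no member was called by limma over all probe sets. None was called adjusted over the list alone either, against 6 that rose with donor as a block. The cell cycle medians within donors 1, 2 and 3 were 0.05, 0.20 and 0.55, and the call was lost without donor 3 (median 0.06, adjusted p = 0.197) or its TGF-β3 array (median 0.10, adjusted p = 0.129). The median was 0.36 without donor 1, and 0.34 and 0.13 without the untreated array of donor 1 or 2. Mesenchymal stromal markers fell, with a median of -0.29 (adjusted p = 0.00214, and adjusted p = 0.0771 with an estimated correlation). Of its 20 members 2 fell, the platelet-derived growth factor receptor genes PDGFRA (-0.84 ± 0.18) and PDGFRB (-0.76 ± 0.13), against 11 that fell and 1 that rose adjusted over the list alone. With the block 7 fell and 1 rose over all probe sets, and 2 rose adjusted over the list alone. Interferon response genes fell, with a median of -0.20 (adjusted p = 0.000609, and adjusted p = 0.403 with an estimated correlation). Among 18 members the antiviral MX1 (-1.43 ± 0.32) and the RNA sensor gene RIGI (-0.64 ± 0.11) fell over all probe sets (4 with the block), and 4 fell adjusted over the list alone (7 with the block).

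Glycolysis genes had a median of 0.18 with TGF-β3 at atmospheric oxygen (adjusted p = 0.0306, and adjusted p = 0.616 with an estimated correlation). The glucose transporter gene SLC2A1 rose by 1.39 ± 0.17 (adjusted p = 0.00145) and was the 1 of 21 members called over all probe sets, against 2 that rose and 2 that fell adjusted over the list alone. The block gave 4 that rose and 1 that fell over all probe sets, and 8 rose adjusted over the list alone. Glycolysis lost its call at 21% without donor 3 (adjusted p = 0.197), its untreated (0.0615) or treated array (0.179), the untreated array of donor 1 (0.0674) or the treated array of donor 2 (0.132). At 2% oxygen glycolysis was not called with TGF-β3 (median 0.15, adjusted p = 0.0928), with 2 members up and 1 down over all probe sets (5 and 2 with the block), and 5 up and 2 down adjusted over the list alone. Hypoxia response genes outside glycolysis had a median of 0.23 (adjusted p = 0.0194, and adjusted p = 0.536 with an estimated correlation). The collagen lysyl hydroxylase gene PLOD2 (1.02 ± 0.098) and VEGFA (0.50 ± 0.12) rose and the lipoprotein receptor gene VLDLR (-0.66 ± 0.14) fell among 29 members, and 5 rose and 2 fell adjusted over the list alone. With the block 7 rose over all probe sets and 11 adjusted over the list alone. The call of the hypoxia list was lost without donor 3 (adjusted p = 0.108), its treated array (0.121), the untreated array of donor 1 (0.0644) or the treated array of donor 2 (0.0523), and its median was 0.36 without donor 1 or its treated array. The fibrous matrix list was not called (adjusted p = 0.0779), with 2 of 29 members up, COL8A1 at 0.94 ± 0.18 among them, and 5 down. The collagen-binding proteoglycan gene DCN (-1.12 ± 0.18), COL14A1 (-0.96 ± 0.20) and COL3A1 (-0.78 ± 0.18) were among those that fell. Adjusted over the list alone, 3 rose and 8 fell. With the block 8 fell over all probe sets, and 5 rose adjusted over the list alone.

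**Figure D1:**
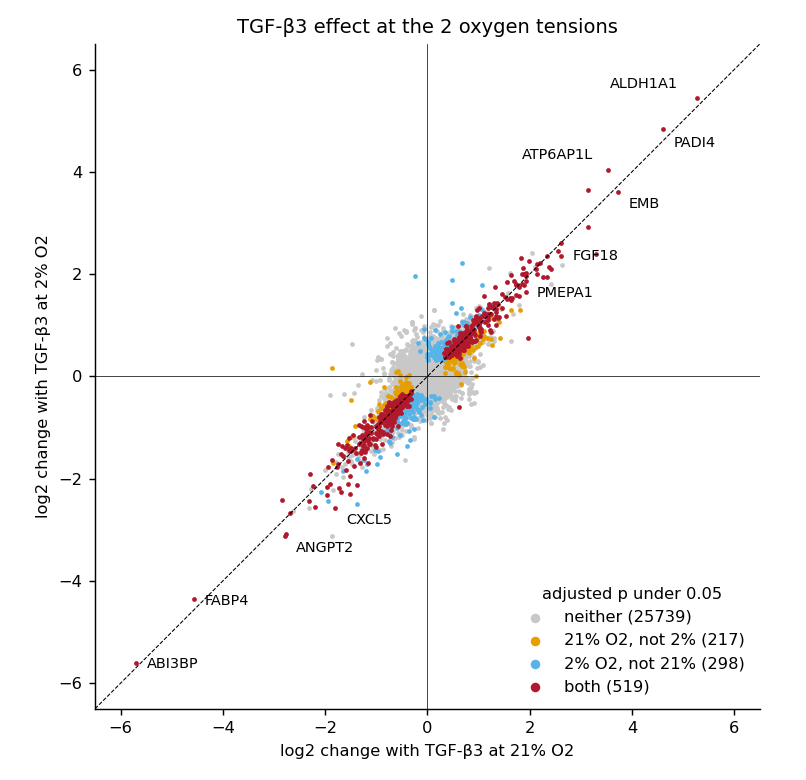
Log2 change with TGF-β3 at 2% oxygen (vertical axis) against that at 21% oxygen (horizontal axis) for 26773 probe sets, coloured by the comparisons in which the adjusted p was under 0.05, with equal change dashed. 519 probe sets passed at both tensions, 217 at 21% and not 2%, and 298 at 2% and not 21%, and ALDH1A1 and ABI3BP lie at the ends of the cloud.

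In hypoxia the largest rise with TGF-β3 was again that of ALDH1A1, which rose by 5.45 ± 0.64 (43.8-fold, adjusted p = 0.00126), and PADI4 rose by 4.83 ± 0.52 (adjusted p = 0.000722). ABI3BP fell by 5.60 ± 0.88 (adjusted p = 0.00604) and FABP4 fell by 4.36 ± 0.52 (adjusted p = 0.00139), to a mean signal of 3.97. CXCL5, a neutrophil-attracting chemokine, fell by 2.58 ± 0.26 (adjusted p = 0.000557). ATP6AP1L (4.04 ± 0.37), PTGER3 (3.64 ± 0.45), EMB (3.60 ± 0.40), PRR5L (2.92 ± 0.25), FGF18 (2.60 ± 0.21) and the lipolysis inhibitor gene G0S2 (2.45 ± 0.33) followed among the rises. ANGPT2 (-3.12 ± 0.28), CYP1B1 (-3.08 ± 0.56), ULBP21 (-2.66 ± 0.40), PRSS35 (-2.56 ± 0.36) and LRRN1 (-2.49 ± 0.48) were the other large falls. In limma, 817 probe sets passed, 387 higher and 430 lower, and 231 changed at least 2-fold. Each had 1 direction in 3 of 3 donors, as did 39.2% of all probe sets. The count was 1869 with donor as a block, 49 without donor 2 and 116 without donor 1. It was 402 or 504 without the treated array of donor 1 or 2 and 454 without the untreated array of donor 2. Of 56 named genes called here, 28 kept the call without any 1 array and 7 (ATP6AP1L, PRR5L, FGF18, ANGPT2, CXCL5, PMEPA1 and MMP19) without any donor, while 40, 46 and 20 lost it without donors 1, 2 and 3. ID2, ATOH8, CA9, VEGFA, SOX9, DES, PALLD, ITGA5 and DKK3 were among those that lost it on leaving out 5 of the 6 arrays in turn, and SOX6 and MX1 among those that did so with each of the 6.

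TGF-β response genes rose in hypoxia with a median of 0.50 (adjusted p = 2.21e-06, and adjusted p = 0.0324 with an estimated correlation). With the donor block as well the latter was 0.135, so that the call was lost. Over all probe sets 8 of 28 rose and 1 fell (14 and 2 with the block), against 16 and 6 adjusted over the list alone, and PMEPA1 (1.87 ± 0.13), TGFB2 (1.24 ± 0.13), SKIL (1.22 ± 0.13) and IL11 (1.22 ± 0.20) had the largest rises. SMAD7 changed by 0.47 ± 0.22 (adjusted p = 0.34, and 0.0241 with donor as a block, in a range of 0.0241 to 0.668 over all alternatives), and TGFBI by 0.84 ± 0.27 (adjusted p = 0.137). Genes of the bone morphogenetic protein (BMP) response fell, with a median of -0.45 and 16 of 18 members below 0 (adjusted p = 2.21e-06, and adjusted p = 0.245 with an estimated correlation). The homeobox genes DLX3 (-1.57 ± 0.25) and DLX5 (-1.52 ± 0.29), ID2 (-1.01 ± 0.22) and ATOH8 (-0.66 ± 0.15) fell over all probe sets, and 9 members fell adjusted over the list alone. With the block 7 fell over all probe sets, and 1 rose adjusted over the list alone. At atmospheric oxygen the BMP list was not called (median -0.13, adjusted p = 0.0556), although its ligand gene BMP4 fell by 1.00 ± 0.22 and 3 members fell adjusted over the list alone. With the block 4 fell over all probe sets, and 6 fell and 1 rose adjusted over the list alone.

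Contractile genes rose in hypoxia with a median of 0.48 (adjusted p = 5.07e-09, and adjusted p = 0.296 with an estimated correlation). Of 21 members, 4 rose over all probe sets, DES (2.22 ± 0.51), TAGLN (0.62 ± 0.12), the transcription factor gene SRF (0.59 ± 0.12) and PALLD (0.53 ± 0.11), against 11 with the block, and 12 adjusted over the list alone. The cell cycle list rose with a median of 0.34 and 27 of 28 members above 0 (adjusted p = 1.33e-05, and adjusted p = 0.545 with an estimated correlation). No member was called by limma over all probe sets or adjusted over the list alone, against 2 and 12 that rose with the block. Cell cycle medians within donors 1, 2 and 3 were 0.09, 0.16 and 0.62, and the median was 0.16 without donor 3 (adjusted p = 0.0325) or its TGF-β3 array (adjusted p = 0.0235). Mesenchymal stromal markers fell with a median of -0.39 (adjusted p = 0.00329, and adjusted p = 0.106 with an estimated correlation). PDGFRB fell by 0.70 ± 0.13 and the fibronectin receptor subunit gene ITGA5 rose by 0.67 ± 0.16, against 7 that fell and 1 that rose adjusted over the list alone. With the block 5 fell over all probe sets, and 11 fell and 2 rose adjusted over the list alone. Interferon response genes fell with a median of -0.10 (adjusted p = 0.00801, and adjusted p = 0.327 with an estimated correlation), with MX1 (-1.39 ± 0.32) and RIGI (-0.61 ± 0.11) down over all probe sets, against 5 with the block, and 5 down adjusted over the list alone. The interferon call was lost without the untreated array of donor 2 (adjusted p = 0.094), and the median was -0.16 without that of donor 1. The hypoxia response list rose with a median of 0.36 (adjusted p = 6.28e-05, and adjusted p = 0.245 with an estimated correlation). The pH-regulating carbonic anhydrase gene CA9 (1.88 ± 0.45), PLOD2 (0.97 ± 0.098) and VEGFA (0.54 ± 0.12) were among 4 of 29 members that rose (9 with the block), VLDLR (-0.76 ± 0.14) was the 1 that fell, and 11 rose adjusted over the list alone.

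Genes of chondrocyte hypertrophy and bone fell with TGF-β3 in hypoxia, with a median of -0.19 and 15 of 18 members below 0 (adjusted p = 0.00211, and adjusted p = 0.245 with an estimated correlation). At 21% the list was not called (median -0.10, adjusted p = 0.18). The median at 2% was -0.11 without donor 3, -0.31 without the untreated array of donor 2 and -0.30 without the treated array of donor 3. DLX5 was the 1 member called over all probe sets, against 4 with donor as a block, and 4 fell adjusted over the list alone, among them the collagenase gene MMP13 (-1.63 ± 0.40) and SP7 (-1.28 ± 0.39), a transcription factor of osteoblasts. Over all probe sets these had adjusted p-values of 0.0543 and 0.117, and 0.00455 and 0.00477 with donor as a block. Matrix proteases and inhibitors fell with a median of -0.18 (adjusted p = 0.00921, and adjusted p = 0.327 with an estimated correlation). MMP19 (-1.50 ± 0.12) and the protease inhibitor gene TIMP3 (-0.59 ± 0.079) fell, and adjusted over the list alone 6 of 23 fell and 2 rose. With the block 4 fell and 2 rose over all probe sets. The protease call was lost without the untreated array of donor 3 (median -0.07, adjusted p = 0.106). At atmospheric oxygen that list was not called (adjusted p = 0.0779), with MMP19 (-1.40 ± 0.12) and TIMP3 (-0.40 ± 0.079) down and the urokinase receptor gene PLAUR (1.64 ± 0.36) up. The cartilage list was called at neither tension (adjusted p = 0.791 at 21% and 0.227 at 2%). The WW domain ubiquitin ligase gene WWP2 rose by 0.53 ± 0.096 at 21%, and the cartilage transcription factor genes SOX6 (-0.81 ± 0.19) and SOX9 (-0.54 ± 0.11, adjusted p = 0.0268) fell at 2%. With the block 4 members fell at 21%, and 5 fell and 2 rose at 2%. SOX9 at 21% changed by -0.04 ± 0.11 (adjusted p = 0.918), and its difference between the tensions did not pass the test (-0.50 ± 0.16, adjusted p = 1). ACAN, which encodes the cartilage proteoglycan aggrecan, changed by -1.27 ± 0.67 at 21% (adjusted p = 0.421, and 0.00327 with donor as a block, in a range of 0.00327 to 0.747 over all alternatives) and by -1.77 ± 0.67 at 2% (adjusted p = 0.214, and 0.000564 with donor as a block, in a range of 0.000564 to 0.56). Within donors 1, 2 and 3 ACAN changed by -1.32, -1.37 and -1.12 at 21%, and by -2.14, -1.70 and -1.46 at 2%. With donor as a block its standard error was 0.175. COL2A1, the cartilage collagen gene, did not pass at 21% (0.74 ± 0.52, adjusted p = 0.575) or 2% (0.91 ± 0.52, adjusted p = 0.456).

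Inflammatory genes moved in both directions with TGF-β3 at both tensions, and the list was not called (adjusted p = 0.489 at 21% and 0.996 at 2%). The cytokine genes IL6 (1.94 ± 0.29 and 1.97 ± 0.29) and LIF (1.54 ± 0.15 and 1.18 ± 0.15) and the hyaluronan-binding TNFAIP6 (1.66 ± 0.28 and 1.53 ± 0.28) rose at 21% and 2%. CXCL5 fell at 21% as well (-1.81 ± 0.26). Adjusted over the list alone, 3 of 20 rose and 1 fell at 21%, and 4 rose and 2 fell at 2%. With the block 2 fell at 21%. Of the Wnt response list, which was not called (adjusted p = 0.0779 and 0.147), the matricellular protein gene CCN4 rose by 1.24 ± 0.15 at 21% and 0.88 ± 0.15 at 2%, and the Wnt antagonist-like gene DKK3 fell by 1.44 ± 0.31 at 2%.

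**Figure D2:**
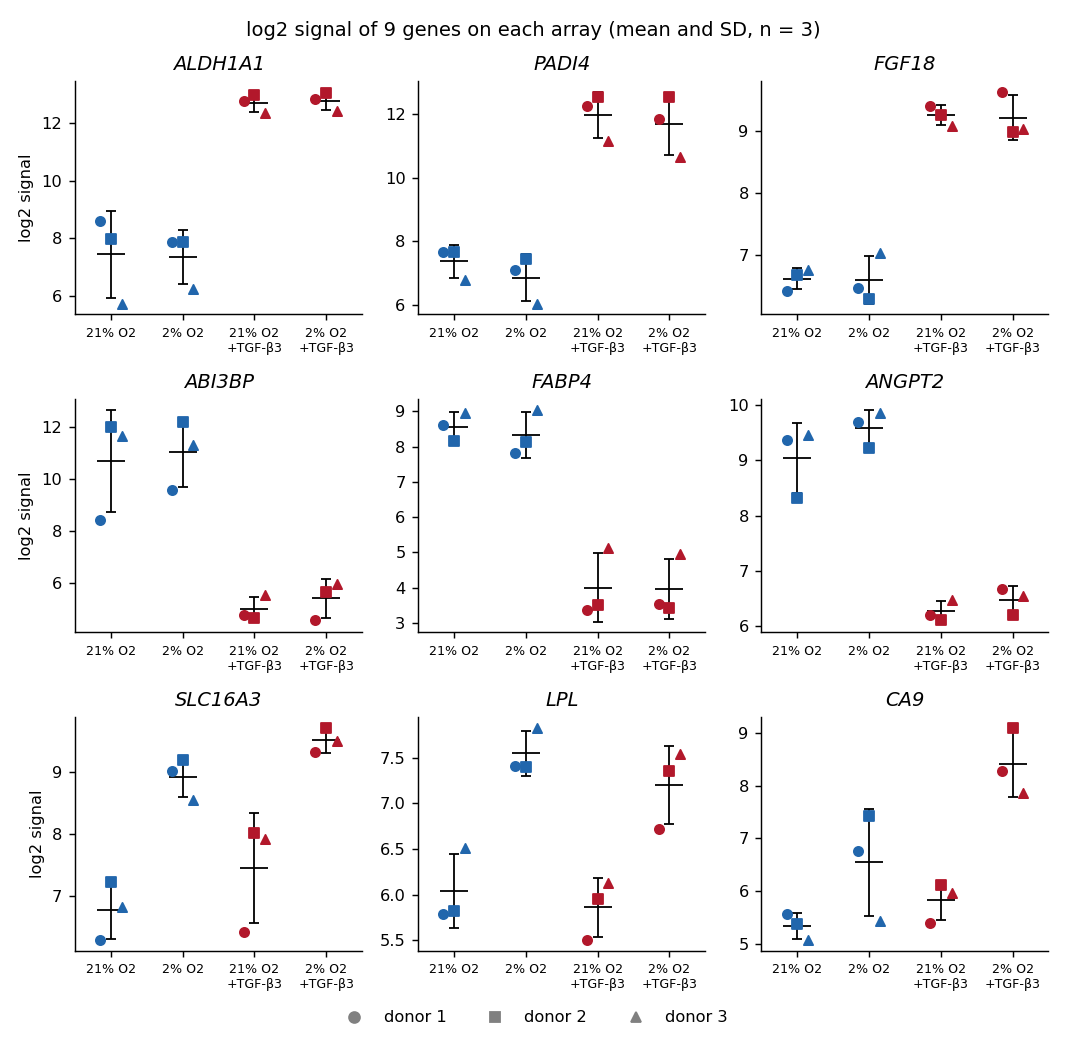
Log2 signal of 9 genes on each array by condition, with blue for no TGF-β3 and red for TGF-β3, a symbol for each donor, and the mean with SD (n = 3). ALDH1A1, PADI4 and FGF18 were higher and ABI3BP, FABP4 and ANGPT2 lower on every TGF-β3 array than on every array without it, and LPL was higher at 2% than at 21% oxygen in each donor with and without TGF-β3.

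The TGF-β3 effects at the 2 tensions, which share no arrays, were set against each other to ask whether oxygen altered the response. FGF18 changed by 2.62 ± 0.21 and 2.60 ± 0.21, and PADI4 by 4.61 ± 0.52 and 4.83 ± 0.52. The interaction for PADI4 was 0.22 ± 0.74 in this fit, which leaves differences between donors in the spread. Within donors 1, 2 and 3 PADI4 changed by 4.597, 4.854 and 4.386 at 21%, and by 4.763, 5.11 and 4.615 at 2%. With donor as a block the standard error of its change at each tension was 0.149. Across probe sets, which are not independent replicates, the log2 changes correlated with Pearson r = 0.751 and Spearman rho = 0.523. Both comparisons called 519 probe sets, 242 higher in both, 276 lower in both and 1 opposite, where independent lists would share 4.94 higher and 6.33 lower. The block gave 1205 shared calls, 532 higher in both, 670 lower in both and 3 opposite, against 25.6 higher and 34 lower for independent lists. Of the 736 called at 21%, 99% had the same sign at 2%. The 1 opposite probe set, 12913307, has no gene named here and was singled out after its values were seen. It changed by 0.62 ± 0.11 at 21% and -0.59 ± 0.11 at 2%. The difference of -1.22 ± 0.15 had an adjusted p of 0.188.

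No probe set passed the test of the interaction between TGF-β3 and oxygen in limma (0 called, smallest adjusted p = 0.188). There were 787 at an unadjusted p under 0.05, which is 2.94% of those tested. The count was also 0 with donor as a fixed or random block, with an intensity trend and with no variance moderation. The count was 1 without the untreated hypoxic array of donor 2. The genes with the smallest p were LAMTOR5 (0.56 ± 0.13), RAB3C (0.73 ± 0.19), UPK1B (0.78 ± 0.20), RIBC2 (-0.60 ± 0.13), CNTNAP4 (-0.77 ± 0.17) and CLDN1 (-0.67 ± 0.15), each with an adjusted p of 1. RIBC2 and CLDN1 had lowest group means of 4.73 and 4.69, below the first quartile of every array (4.89 to 4.98). The BMP response list was the 1 list called, with a median interaction of -0.30 and 17 of 18 members below 0 (adjusted p = 5.88e-05, and adjusted p = 0.74 with an estimated correlation). No BMP response member was called by limma over all probe sets or adjusted over the list alone. With donor as a block 2 lists were called, the other being chondrocyte hypertrophy and bone (median -0.15, adjusted p = 0.0603, and 0.0138 with the block). Neither list was called when an estimated correlation was used with the block. Without the hypoxic array of donor 3 that had no TGF-β3 the count of lists was 0 (BMP response, median -0.23, adjusted p = 0.0639), and without its hypoxic TGF-β3 array it was 4. It was 3 without any normoxic TGF-β3 array, the hypoxic untreated array of donor 2 or the normoxic untreated array of donor 3. It was 2 without either hypoxic array of donor 1, the normoxic untreated or hypoxic TGF-β3 array of donor 2, or all arrays of donor 2 or of donor 3. The BMP median was -0.19 without the untreated hypoxic array of donor 1.

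Hypoxia without TGF-β3 raised CNTNAP4, a neurexin-family cell adhesion gene, by 1.43 ± 0.12 (2.69-fold, adjusted p = 0.00345, higher in 3 of 3 donors). It was the 1 probe set that passed over all probe sets in limma, with 1447 at an unadjusted p under 0.05 (2253 with donor as a block). The 1447 are 5.4% of those tested, near the share of 0.05 due if nothing changed. With donor as a block 3 passed, and the others, named after their values were seen, were the lipoprotein lipase gene LPL (1.5 ± 0.26, adjusted p = 0.29, and 0.00741 with the block) and B4GALT6, a glycosphingolipid synthesis gene (-1.15 ± 0.38, adjusted p = 0.835, and 0.00741 with the block). Leaving out any donor gave 0, and leaving out the untreated hypoxic array of donor 2 gave 2. The glycolysis list rose, with all 21 members above 0 and a median of 0.36 (adjusted p = 2.16e-24, and adjusted p = 0.0419 with an estimated correlation). None of the 21 passed over all probe sets, and 15 rose adjusted over the list alone, with the lactate exporter gene SLC16A3 at 2.14 ± 0.38, SLC2A1 at 0.87 ± 0.17, PFKL at 0.86 ± 0.20 and PFKFB3 at 0.72 ± 0.12. The hypoxia response list outside glycolysis rose with a median of 0.28 and 26 of 29 members above 0 (adjusted p = 1.02e-12, and adjusted p = 0.0419 with an estimated correlation). Adjusted over the list alone 12 rose, among them CA9 (1.21 ± 0.45), the vasodilator peptide gene ADM (0.94 ± 0.34) and the lipoprotein lipase inhibitor gene ANGPTL4 (0.93 ± 0.23). With an estimated correlation and the donor block together both calls were lost (adjusted p = 0.0814 each). The 3 checks of the treatment did not pass over all probe sets, with VEGFA at 0.33 ± 0.12 (adjusted p = 0.879), the pyruvate dehydrogenase kinase gene PDK1 at 0.65 ± 0.17 (adjusted p = 0.702) and NDRG1 at 0.41 ± 0.15 (adjusted p = 0.893).

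Other lists moved with hypoxia without TGF-β3, none with a member called over all probe sets. The inflammatory list rose with a median of 0.19 (adjusted p = 0.0017, adjusted p = 0.0419 with an estimated correlation, and 0.0814 with the donor block as well), and 1 of 20 members rose adjusted over the list alone, CXCL5 at 1.01 ± 0.26. Chondrocyte hypertrophy and bone rose with a median of 0.27 and 14 of 18 members above 0 (adjusted p = 0.000283, and adjusted p = 0.146 with an estimated correlation), and adjusted over the list alone none was called, against 5 that rose with the block. Cartilage genes rose with a median of 0.12 (adjusted p = 0.00144, and adjusted p = 0.278 with an estimated correlation), and adjusted over the list alone the matrix protein gene CILP2 (0.59 ± 0.14) and SOX9 (0.43 ± 0.11) rose, against 5 members with donor as a block. ACAN (0.85 ± 0.67) and COL2A1 (-0.04 ± 0.52) did not pass. The BMP response list rose with a median of 0.20 (adjusted p = 0.000558, and adjusted p = 0.328 with an estimated correlation), and SMAD9 (0.42 ± 0.097) was the 1 member that rose adjusted over the list alone, against 2 with the block. Genes of the unfolded protein and amino acid stress response fell, with 18 of 19 members below 0 and a median of -0.27 (adjusted p = 0.0002, and adjusted p = 0.574 with an estimated correlation). The cell cycle list rose with a median of 0.09 (adjusted p = 0.0479, and adjusted p = 0.647 with an estimated correlation). Oxidative phosphorylation fell with a median of -0.04 (adjusted p = 0.0479, 0.0508 with donor as a block, and adjusted p = 0.603 with an estimated correlation). Contractile (median -0.08, adjusted p = 0.0756) and sterol synthesis genes (median -0.15, adjusted p = 0.105) were called with the block alone (adjusted p = 0.0265 and 0.0399). Both were lost when an estimated correlation was used as well. Erythroid markers, expressed by red cell precursors of the marrow, fell with all 9 members below 0 and a median of -0.10 (adjusted p = 0.0213, and adjusted p = 0.309 with an estimated correlation). Of these calls, BMP response was lost without donor 3 (adjusted p = 0.148) or its hypoxic array (0.157), and its median was 0.32 without the hypoxic array of donor 2. Erythroid markers lost the call without donor 3 or either of its arrays (adjusted p = 0.0854 to 0.281). Oxidative phosphorylation lost it without donor 1, either of its arrays, donor 2, its hypoxic array or the normoxic array of donor 3 (adjusted p = 0.0882 to 0.377). Cell cycle lost it without donor 2 or 3, either array of donor 3, the hypoxic array of donor 1 or the normoxic array of donor 2 (adjusted p = 0.132 to 0.915), and its median was 0.20 and 0.14 without the normoxic array of donor 1 or the hypoxic array of donor 2. The cartilage median was 0.08 without the hypoxic array of donor 1 or the normoxic array of donor 2, and that of the unfolded protein list -0.17 without the hypoxic array of donor 1. Regrouping the same 6 arrays in 9 other ways, which keeps part of the treatment difference, called a median of 5 lists, against 10 here.

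Hypoxia in the presence of TGF-β3 gave its smallest p-values for SRL, a calcium-binding protein gene of the sarcoplasmic reticulum (0.91 ± 0.13), the glycolytic regulator gene PFKFB3 (0.82 ± 0.12), the mitochondrial carbonic anhydrase gene CA5B (0.93 ± 0.14) and, among falls, the magnesium channel gene TRPM6 (-1.12 ± 0.21), MARCHF1 (-0.58 ± 0.12) and RPL10L (-0.42 ± 0.10). The lower group mean was 3.80 for MARCHF1 and 4.61 for RPL10L, below the first quartile of every array. None passed, with limma calling 0 probe sets, 1152 at an unadjusted p under 0.05 (1862 with donor as a block) and a smallest adjusted p of 0.199. The 1152 are 4.3% of those tested, below the share of 0.05 due if nothing changed. With donor as a block 6 were called, all higher, among them the hyaluronan synthase gene HAS2 (1.18 ± 0.31, adjusted p = 0.0354 with the block), LPL (1.34 ± 0.26, adjusted p = 0.0349 with the block) and CA5B (adjusted p = 0.0417 with the block). Without donor 3, or without its normoxic TGF-β3 array alone, 2 were called, and the fits with an intensity trend, no variance moderation or a random donor block called 0. The glycolysis list rose with a median of 0.32 and 20 of 21 members above 0 (adjusted p = 5.96e-23, and adjusted p = 0.0375 with an estimated correlation). Adjusted over the list alone 15 rose, with SLC16A3 at 2.05 ± 0.38, SLC2A3 at 1.67 ± 0.59 and PFKL at 0.87 ± 0.20. The hypoxia response list rose with a median of 0.43 and 28 of 29 members above 0 (adjusted p = 2.68e-22, and adjusted p = 0.0187 with an estimated correlation). Adjusted over the list alone 15 rose, with CA9 at 2.60 ± 0.45, ADM at 1.39 ± 0.34 and FAM162A at 0.89 ± 0.20. With an estimated correlation and the donor block together the hypoxia response list passed (adjusted p = 0.0355) and glycolysis did not (adjusted p = 0.142). VEGFA (0.37 ± 0.12), PDK1 (0.77 ± 0.17), NDRG1 (0.53 ± 0.15), SOX9 (-0.06 ± 0.11), ACAN (0.35 ± 0.67) and COL2A1 (0.12 ± 0.52) did not pass over all probe sets.

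Of the remaining lists in hypoxia with TGF-β3, the unfolded protein and amino acid stress response fell with a median of -0.25 and 18 of 19 members below 0 (adjusted p = 2.14e-05, and adjusted p = 0.565 with an estimated correlation). The cell cycle list rose with a median of 0.15 (adjusted p = 0.00073, and adjusted p = 0.711 with an estimated correlation), and oxidative phosphorylation fell with a median of -0.06 (adjusted p = 0.0377, and adjusted p = 0.565 with an estimated correlation). Cartilage (median 0.08, adjusted p = 0.15) and collagen modification and crosslinking (median 0.10, adjusted p = 0.0729) were called with the donor block alone (adjusted p = 0.0379 each). An estimated correlation used with the block gave a call for neither. The unfolded protein list lost its call without the hypoxic array of donor 3 (median -0.03, adjusted p = 0.393), with a median of -0.16 without the normoxic array of donor 2. Cell cycle lost it without either of these arrays (adjusted p = 0.966 and 0.594), and had medians of 0.30 and 0.26 without the hypoxic array of donor 2 or the normoxic array of donor 3. Oxidative phosphorylation lost it without donor 2, the hypoxic array of donor 1 or 2 or the normoxic array of donor 3 (adjusted p = 0.214 to 0.563), and had a median of -0.11 without the hypoxic array of donor 3. The hypoxia effects without and with TGF-β3, which share no arrays, correlated across probe sets with Pearson r = 0.282 and Spearman rho = 0.216.

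Averaged over both TGF-β3 states, hypoxia raised SLC16A3 by 2.10 ± 0.27 (4.27-fold, adjusted p = 0.0187) and LPL by 1.42 ± 0.18 (2.68-fold, adjusted p = 0.0187). CNTNAP4 rose by 1.04 ± 0.086 (adjusted p = 0.00244), ADIRF, a regulator of adipogenesis, by 0.89 ± 0.13 (adjusted p = 0.0426) and the ribonuclease gene RNASE4 by 0.89 ± 0.10 (adjusted p = 0.0167). Limma called 13 probe sets, 12 higher and 1 lower, each with 1 direction in 3 of 3 donors, as held for 35.6% of all probe sets. The others with a name were CA5B (0.82), PFKFB3 (0.77), SRL (0.73), PATJ (0.60), the clock gene ARNTL (0.50) and the glycolytic enzyme gene GPI (0.48). The remaining 2, probe sets 12910555 (0.69 ± 0.093) and 12835869 (-0.53 ± 0.061), have no gene named here, and the latter was the 1 that fell. With donor as a block 83 passed, 70 higher and 13 lower. The added ones included NDUFA4L2, a mitochondrial protein gene induced by hypoxia (2.91 ± 0.47, adjusted p = 0.0721, and 0.0235 with the block), CA9 (1.90 ± 0.32, adjusted p = 0.0742, and 0.0216 with the block) and, among falls, EPAS1, which encodes a hypoxia-inducible factor subunit (-0.66 ± 0.13, adjusted p = 0.147, and 0.0287 with the block). These 3 were picked after their values were seen. Without donor 1 or 2 the count was 0, and without donor 3 it was 2. It was 1 without the normoxic untreated array of donor 1 or 2 or the hypoxic untreated array of donor 1. It was 2 without the hypoxic TGF-β3 array of donor 1 or 3 and 3 without that of donor 2. It was 8 without the normoxic TGF-β3 or hypoxic untreated array of donor 2, and 21 without the normoxic TGF-β3 array of donor 3. Of the 5 genes taken by the rule, CNTNAP4 was the 1 that kept its call without any 1 array, and 0 kept it without any donor.

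Averaged over TGF-β3, 17 of 21 glycolysis genes and 19 of 29 hypoxia response genes rose adjusted over the list alone, against 3 and 0 over all probe sets (SLC16A3, PFKFB3 and GPI being the 3). The block gave 10 and 3 over all probe sets. The medians were 0.31 and 0.35 (adjusted p = 1.54e-29 and 1.15e-22, and adjusted p = 0.0176 with an estimated correlation for each). With the block as well the latter were 0.0938 and 0.0395, so that the call of glycolysis was lost. The unfolded protein and amino acid stress list fell with all 19 members below 0 and a median of -0.28 (adjusted p = 5.94e-07, and adjusted p = 0.363 with an estimated correlation), and sterol synthesis fell with a median of -0.12 (adjusted p = 0.0374, and adjusted p = 0.67 with an estimated correlation). Oxidative phosphorylation fell (median -0.05, adjusted p = 0.00631, and adjusted p = 0.364 with an estimated correlation), as did erythroid markers (median -0.08, adjusted p = 0.0209, and adjusted p = 0.321 with an estimated correlation). Cartilage (median 0.08, adjusted p = 0.00377, and adjusted p = 0.321 with an estimated correlation) and chondrocyte hypertrophy and bone (median 0.16, adjusted p = 0.00377, and adjusted p = 0.321 with an estimated correlation) rose. Cell cycle (median 0.12, adjusted p = 0.000908, and adjusted p = 0.67 with an estimated correlation) and inflammatory genes (median 0.10, adjusted p = 0.00631, and adjusted p = 0.0766 with an estimated correlation) rose too, with the prostaglandin E synthase gene PTGES (0.67 ± 0.15) the 1 member called adjusted over the list alone, against 3 that rose and 1 that fell with the block. Collagen modification and crosslinking was called with the block alone (adjusted p = 0.0519, and 0.0377 with the block), and not with an estimated correlation as well. Sterol synthesis lost its call without donor 2 or 3, the hypoxic TGF-β3 array of donor 1, either normoxic array of donor 2, or the normoxic TGF-β3 or hypoxic untreated array of donor 3 (adjusted p = 0.0789 to 0.454). Its median was -0.18 without donor 1 or the normoxic untreated array of donor 3, and -0.20 without the normoxic TGF-β3 array of donor 1. Oxidative phosphorylation lost it without donor 2, its hypoxic TGF-β3 array or the normoxic TGF-β3 array of donor 3 (adjusted p = 0.0853 to 0.202), and had a median of -0.03 without the hypoxic untreated array of donor 2. Erythroid markers lost it without donor 1 or 3, the normoxic TGF-β3 array of donor 1 or the hypoxic untreated array of donor 3 (adjusted p = 0.0833 to 0.26), with a median of -0.14 without donor 2. Cell cycle lost it without the normoxic TGF-β3 array of donor 2 (adjusted p = 0.103) or the hypoxic TGF-β3 array of donor 3 (0.225), with a median of 0.08 without the hypoxic untreated array of donor 1. The unfolded protein median was -0.12 without the hypoxic TGF-β3 array of donor 3, and that of hypertrophy and bone 0.10 without the normoxic TGF-β3 array of donor 2. For cartilage it was 0.04 without the hypoxic TGF-β3 array of donor 2, and 0.12 to 0.14 without donor 3, its normoxic untreated or hypoxic TGF-β3 array, the normoxic TGF-β3 array of donor 1 or the normoxic untreated array of donor 2.

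**Figure D3:**
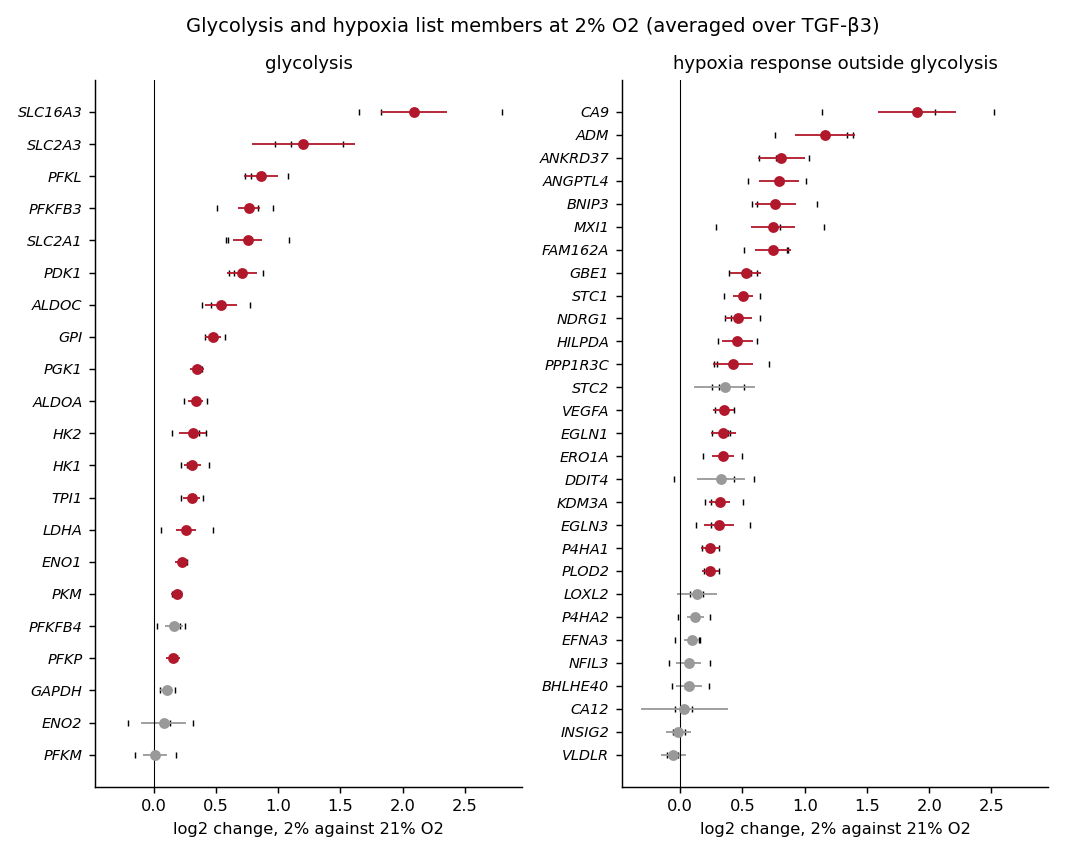
Log2 change at 2% against 21% oxygen, averaged over TGF-β3, for 21 glycolysis and 29 hypoxia response genes, with the standard error as a bar, each donor as a tick, and red for adjusted p under 0.05 over the list alone. SLC16A3 at 2.10 and CA9 at 1.90 lead the lists, of which 17 and 19 members are red.

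Averaged over oxygen, TGF-β3 raised ALDH1A1 by 5.36 ± 0.45 (41.1-fold, adjusted p = 4.57e-05), PADI4 by 4.72 ± 0.37, ATP6AP1L by 3.79 ± 0.26, EMB by 3.66 ± 0.29 and PTGER3 by 3.39 ± 0.32. ABI3BP fell by 5.65 ± 0.62 (adjusted p = 0.000262). FABP4 (-4.46 ± 0.37), ANGPT2 (-2.95 ± 0.20), CYP1B1 (-2.92 ± 0.40) and ULBP21 (-2.67 ± 0.29) fell too. Limma called 2582 probe sets, 1245 higher and 1337 lower, and 3954 with donor as a block. The count was 593 without donor 2, 826 without donor 1 and 1609 without donor 3. All 10 genes named here kept their call without any 1 array, and 9 without any donor, CYP1B1 losing it without donor 2. TGF-β response genes rose (median 0.53, adjusted p = 4.54e-06, adjusted p = 0.0348 with an estimated correlation, and 0.1 with the donor block as well), 17 of 28 members rising and 4 falling over all probe sets, against 18 and 6 adjusted over the list alone. Contractile genes rose (median 0.40, adjusted p = 7.28e-09, and adjusted p = 0.253 with an estimated correlation), 12 of 21 over all probe sets and 14 adjusted over the list alone. BMP response genes fell (median -0.30, adjusted p = 0.000351, and adjusted p = 0.253 with an estimated correlation), with 8 of 18 members down over all probe sets and 10 adjusted over the list alone, among them DLX3 (-1.25 ± 0.18) and BMP2 (-1.22 ± 0.28). Mesenchymal stromal markers fell (median -0.30, adjusted p = 0.000956, and adjusted p = 0.0642 with an estimated correlation), with the stromal chemokine gene CXCL12 (-1.17 ± 0.27) and NT5E (-1.01 ± 0.24), which encodes CD73, among 8 of 20 down over all probe sets and 12 adjusted over the list alone. The other lists called were cell cycle (median 0.30, adjusted p = 1.03e-05), hypoxia response (0.26, adjusted p = 0.000554) and glycolysis (0.16, adjusted p = 0.0352), which rose, and interferon response (-0.13, adjusted p = 0.000956), hypertrophy and bone (-0.16, adjusted p = 0.0112) and proteases (-0.16, adjusted p = 0.0215), which fell. None of these 6 was called with an estimated correlation (adjusted p = 0.253 to 0.615). Without donor 3 the cell cycle median was 0.12 and that of hypertrophy and bone -0.08. Glycolysis lost its call without donor 2 or 3, the normoxic untreated array of donor 1, or the normoxic TGF-β3 array of donor 2 or 3 (adjusted p = 0.0503 to 0.101). Proteases lost it without the normoxic TGF-β3 array of donor 1 or either untreated array of donor 3 (adjusted p = 0.0542 to 0.0605). Fibrous matrix and sterol synthesis were called with the donor block alone (adjusted p = 0.0614 and 0.0515, and 0.0457 and 0.0338 with the block). Neither call held with an estimated correlation as well. The averaged TGF-β3 and hypoxia effects correlated across probe sets with Pearson r = -0.0486. They shared 8 of the 13 probe sets called for hypoxia, 2 higher in both, 1 lower in both and 5 opposite, where independent lists would share 0.558 higher and 0.0499 lower. With the block the balance turned, as 51 were shared, 26 higher in both, 5 lower in both and 20 opposite, against 5.11 higher and 0.971 lower for independent lists.

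Cells given both treatments were set against cells given neither. ALDH1A1 rose by 5.35 ± 0.64 (adjusted p = 0.00116), PADI4 by 4.32 ± 0.52, EMB by 4.25 ± 0.40, ATP6AP1L by 4.04 ± 0.37 and DPT by 3.74 ± 0.48. ABI3BP fell by 5.28 ± 0.88 (adjusted p = 0.00763). FABP4 (-4.60 ± 0.52), the transmembrane glycoprotein gene GPNMB (-2.91 ± 0.66), SVEP1 (-2.67 ± 0.24) and the podoplanin gene PDPN (-2.63 ± 0.60) fell too. Limma called 1002 probe sets, 505 higher and 497 lower, and 2046 with donor as a block. Without donors 1, 2 and 3 the count was 169, 101 and 485, without the doubly treated array of donor 1 or 2 it was 526 or 620, and without the control array of donor 2 or 3 it was 455 or 453. Of the 10 genes named here, 8 kept the call without any 1 array and 3 (EMB, ATP6AP1L and SVEP1) without any donor. Hypoxia response genes rose (median 0.64, adjusted p = 1.02e-13, adjusted p = 0.0395 with an estimated correlation, and 0.0845 with the donor block as well), 13 of 29 members rising and 1 falling over all probe sets, against 19 and 1 adjusted over the list alone. Glycolysis genes rose (median 0.46, adjusted p = 4.85e-12, and adjusted p = 0.107 with an estimated correlation), 12 of 21 over all probe sets and 14 adjusted over the list alone. TGF-β response genes rose (median 0.59, adjusted p = 8.68e-08, adjusted p = 0.0175 with an estimated correlation, and 0.0845 with the donor block as well), 12 of 28 rising and 1 falling (2 with the block) over all probe sets, against 17 and 3 adjusted over the list alone. Cell cycle genes rose with all 28 members above 0 (median 0.41, adjusted p = 3.47e-08, and adjusted p = 0.366 with an estimated correlation), 1 over all probe sets, against 9 with the block, and 13 adjusted over the list alone. Collagen modification and crosslinking rose (median 0.13, adjusted p = 0.0121, and adjusted p = 0.366 with an estimated correlation), and sterol synthesis fell with all 13 members below 0 (median -0.24, adjusted p = 0.00641, and adjusted p = 0.492 with an estimated correlation). Contractile genes rose as well (median 0.29, adjusted p = 1.04e-06), while BMP response (-0.18), mesenchymal stromal (-0.27) and interferon response genes (-0.12, adjusted p = 0.00709 each) and the unfolded protein list (-0.16, adjusted p = 0.0157) fell. None of these 5 was called with an estimated correlation (adjusted p = 0.107 to 0.548). The unfolded protein list lost its call without donor 3 (median 0.04, adjusted p = 0.953), its doubly treated array (median -0.02, adjusted p = 0.659) or its control array (adjusted p = 0.0564). Its median was -0.27 without donor 1 or the doubly treated array of donor 2, and -0.25 without donor 2. Sterol synthesis lost it without donor 1, its doubly treated array or the control array of donor 2 (adjusted p = 0.0528 to 0.148), with medians of -0.38 and -0.36 without donor 3 or its control array. Collagen modification lost it without donor 1 or 2, the control array of donor 1 or the doubly treated array of donor 2 (adjusted p = 0.077 to 0.13). Interferon response lost it without the control array of donor 2 (adjusted p = 0.0633), with a median of -0.18 without its doubly treated array. The cell cycle median was 0.24 without donor 3, and that of BMP response -0.29 without the doubly treated array of donor 1.

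**Figure D4:**
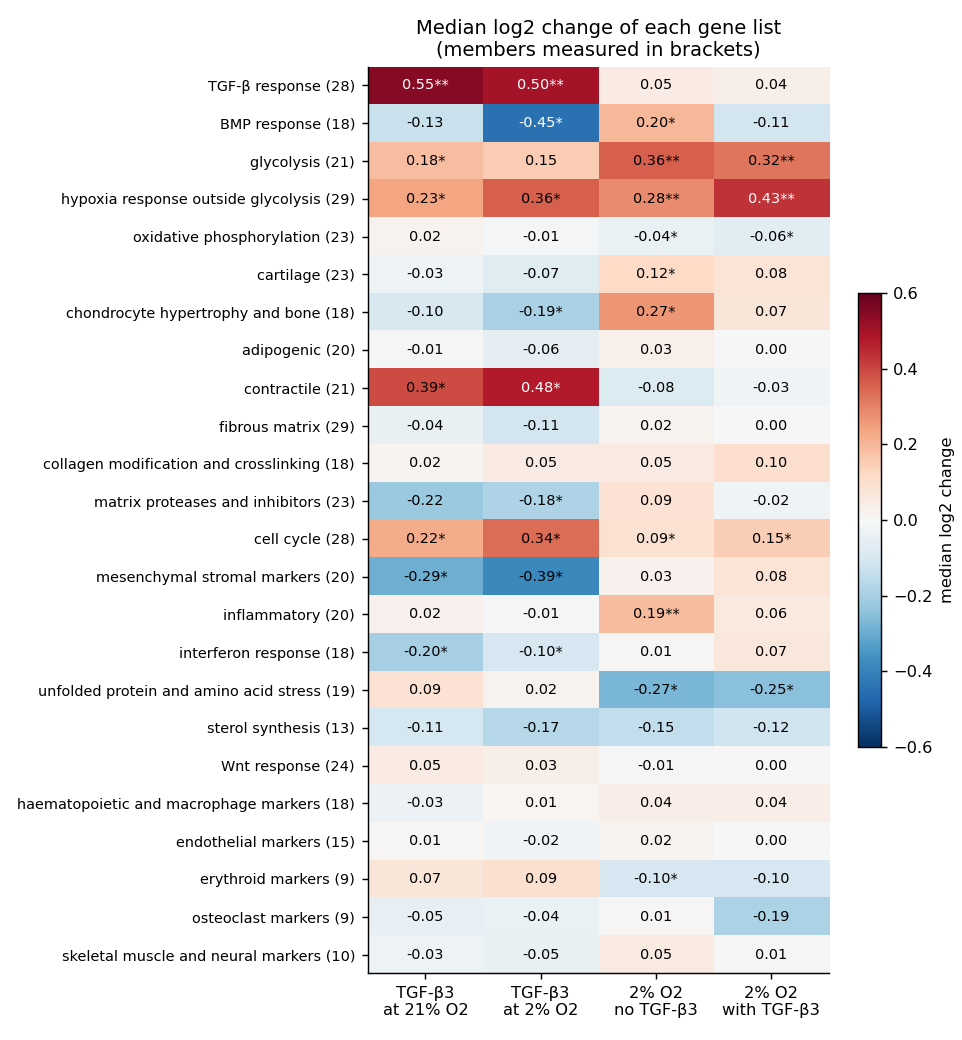
Median log2 change of the measured members of 24 gene lists (number in brackets) in 4 comparisons, with 1 star for an adjusted p under 0.05 in camera with the preset correlation and 2 stars where this also held with an estimated correlation. Glycolysis (0.36 and 0.32) and hypoxia response genes (0.28 and 0.43) carry 2 stars in both hypoxia comparisons, and TGF-β response genes in both TGF-β3 comparisons, while with the donor block added to the estimated correlation only the hypoxia response list in hypoxia with TGF-β3 passed (adjusted p = 0.0355) in the 4 comparisons drawn.

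Markers of other marrow cell types were tested in the same way. Haematopoietic and macrophage markers were not called with TGF-β3 at 21% (median -0.03, adjusted p = 0.791) or 2% (0.01, adjusted p = 0.996), nor in hypoxia without TGF-β3 (0.04, adjusted p = 0.458) or with it (0.04, adjusted p = 0.255). Osteoclast markers (medians -0.05, -0.04, 0.01 and -0.19 in the same order) and skeletal muscle and neural markers (-0.03, -0.05, 0.05 and 0.01) were not called either, with adjusted p-values of at least 0.222. Endothelial markers were not called as a list (adjusted p = 0.265 at 21% and 0.51 at 2%), but PECAM1 rose with TGF-β3 by 2.13 ± 0.25 at 21% and 2.11 ± 0.25 at 2%, and the VEGF receptor gene FLT1 by 0.85 ± 0.20 and 0.99 ± 0.20. These were the 2 of 15 members called, over all probe sets and adjusted over the list alone. The adipogenic list was not called with TGF-β3 (adjusted p = 0.265 at 21% and 0.132 at 2%), and FABP4 was the 1 of its 20 members called over all probe sets at each tension, against 2 with the block.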

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

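The tests given in this part were chosen before the result was seen. The effect of TGF-β3 on the BMP response list differed between the oxygen tensions by a test of the difference itself (camera on the interaction at a preset correlation, adjusted p = 5.88e-05), but not with an estimated correlation between members (adjusted p = 0.74) or with fry (adjusted p = 0.974). The median interaction was -0.30, and 17 of 18 members lay below 0, where the median change with TGF-β3 was -0.13 at 21% and -0.45 at 2% oxygen. The list count was 1, and 0 without the untreated hypoxic array of donor 3. Regrouping the arrays called at least 1 list for the interaction in 97 of 100 splits, the real one included, with up to 10 lists in another split. Those splits also mix TGF-β3 states and donors over the groups, so they give no rate for chance, which is not excluded for this count of 1.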

How the results depend on the processing

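Camera with an estimated correlation together with the donor block, the 2-fold threshold with the donor block, and the alternatives for list examples, were the tests chosen only after the result was seen. Causes were not tested except where an alternative leaves out arrays or probe sets by construction. Signal over background was not measured, so what it limits is unknown. Leaving out probe sets below the median signal, which leaves fewer to test, gave 1124 calls for TGF-β3 at 21%, 0 for hypoxia without TGF-β3 and 29 for averaged hypoxia, and 8 lists for hypoxia with TGF-β3 and 3 for the interaction. The correlations between the paired effects were then 0.886 for TGF-β3 and 0.521 for hypoxia. Rescaling moved the median of all probe sets by at most 0.0334 in size, and equal array medians gave 2 lists for the interaction.

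With donor, from which the pairing comes, as a block, calls were 1701 and 1869 for TGF-β3 at 21% and 2%, 3 and 6 for hypoxia without and with TGF-β3, 2046 for both against neither, 3954 for averaged TGF-β3 and 83 for averaged hypoxia, and 2 lists were called for the interaction. Among named genes 39 calls were gained with the block and none lost, and among lists 8 were gained and 1 lost. Leaving out an array ended the call in 331 of the comparisons of a named or example gene with an alternative and gave a call in 22, and leaving out a donor in 282 and 13. No variance moderation ended 63, and only the 2 groups compared 38 with 2 gained. Apart from these gains and the loss, the donor block changed no other call of a named or example gene or of a list. A random donor block gave 1382, 1559, 1659 and 49 calls for TGF-β3 at 21%, at 2%, both against neither and averaged hypoxia. Using only the 2 groups compared, with fewer arrays to estimate the spread, gave 415, 318 and 647 for the first 3 of these and 0 for hypoxia without TGF-β3. No variance moderation gave 0 for hypoxia without TGF-β3 and 3 for averaged hypoxia, for which an intensity trend gave 26 and 1 probe set per symbol 21. At least 2-fold changes numbered 203, 231, 273, 302 and 3 for TGF-β3 at 21% and 2%, both against neither, averaged TGF-β3 and averaged hypoxia, and 306, 345, 350, 327 and 15 with the donor block, which gave 3 and 2 for hypoxia without and with TGF-β3.

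With an estimated correlation camera called 1 list for TGF-β3 at 21%, 1 at 2%, 3 for hypoxia without and 2 with TGF-β3, 2 for both against neither, 0 for the interaction, 1 for averaged TGF-β3 and 2 for averaged hypoxia. With the block as well these were 0, 0, 0, 1, 0, 0, 0 and 1. Fry called 3 lists for hypoxia without TGF-β3, 2 with it, 0 for the interaction and 3 for averaged hypoxia.

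Leaving out 1 array gave 282 to 598 calls for TGF-β3 at 21%, 402 to 606 at 2%, 1 to 2 and 0 to 2 for hypoxia without and with TGF-β3, 453 to 851 for both against neither, 0 to 1 for the interaction, 1770 to 2309 for averaged TGF-β3 and 1 to 21 for averaged hypoxia. Lists called were 6 to 8, 9 to 11, 7 to 10, 5 to 6, 9 to 12, 0 to 4, 9 to 12 and 8 to 12 in the same order. Leaving out 1 donor gave 29 to 447, 49 to 545, 0, 0 to 2, 101 to 485, 0, 593 to 1609 and 0 to 2 calls, and 7 to 8, 9 to 14, 8 to 10, 4 to 6, 9 to 12, 1 to 2, 9 to 15 and 9 to 10 lists. The 14 lists for TGF-β3 at 2% were without donor 3. The correlations were 0.633 to 0.745 for TGF-β3 (0.633 without donor 2, 0.655 without donor 3), 0.148 to 0.243 for hypoxia (0.148 without donor 2) and -0.141 to 0.0217 between the averaged effects (-0.141 without donor 3).

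Direction was reversed in a few of these fits, and the cause was not tested. SOX9 with TGF-β3 at 21%, not called, ranged from -0.131 to 0.065 over all such fits, and was at 0.031 without the untreated array of donor 3 and 0.065 without donor 3. COL2A1 in hypoxia without TGF-β3, not called, ranged from -0.261 to 0.211, and was at 0.211, 0.095 and 0.049 without the normoxic array of donor 1 or the hypoxic array of donor 2 or 3, and 0.029 without donor 2. In hypoxia with TGF-β3, ACAN, not called, ranged from -0.262 to 0.881, and was at -0.137 without the normoxic array of donor 1 and -0.262 without the hypoxic array of donor 3. COL2A1 there, not called, ranged from -0.406 to 0.659, and was at -0.204, -0.086 and -0.406 without the hypoxic array of donor 1 or 2 or the normoxic array of donor 3. Without the hypoxic TGF-β3 array of donor 3, camera's direction turned for the cell cycle list in hypoxia with TGF-β3 (median 0.003 in a range of 0.003 to 0.296, adjusted p = 0.966, the call being lost) and the unfolded protein list in the interaction (median 0.15 in a range of -0.171 to 0.15, adjusted p = 0.00887, from no call). List values called in no setting compared were not counted as reversed, and 184 of 2200 such values changed direction.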

Other observations

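Of the tests given here, the comparison of counts without and with a donor block was chosen only after the result was seen, and so were the genes singled out. With donor as a block, PDK1 (0.71 ± 0.12, adjusted p = 0.0807, and 0.0087 with the block), SLC2A1 (0.76 ± 0.12, adjusted p = 0.0654, and 0.0413 with the block) and HAS2 (0.81 ± 0.22, adjusted p = 0.383, and 0.0149 with the block) passed for hypoxia averaged over TGF-β3. B4GALT6 changed by -0.95 ± 0.27 (adjusted p = 0.41, and 0.00196 with the block).

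The list of hypoxia response genes outside glycolysis rose with TGF-β3 at both oxygen tensions at the preset correlation, but was not called with an estimated one (adjusted p = 0.536 at 21% and 0.245 at 2%). Overlap with other lists does not account for the call at the preset correlation. For averaged TGF-β3 the 24 members on no other list still gave a camera p of 7.29e-05 and a median of 0.31. With an estimated correlation their camera p was 0.0557, and the whole list was not called there either. A hypothesis that stays open is that cells under TGF-β3 may have met less oxygen. Over the 50 members of the glycolysis and hypoxia lists, the TGF-β3 and hypoxia effects, which are orthogonal contrasts, correlated with Spearman rho = 0.326 (permutation p = 0.0218, bootstrap interval 0.0381 to 0.596, across genes that are not independent). The 4 members that fell with averaged TGF-β3, ADM (-1.01 ± 0.24), VLDLR (-0.71 ± 0.099), ALDOC (-0.66 ± 0.13) and PFKFB4 (-0.40 ± 0.074), run against it, where 6 glycolysis and 10 hypoxia members rose, while probe sets called for both averaged effects (r = -0.0486 over all probe sets) went both ways (5 of 8 opposite, and 20 of 51 with donor as a block), and no other biological explanation was tested.

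Few probe sets were called under hypoxia while both hypoxia lists rose. A donor that did not respond is argued against by the 6 medians within donors over the 50 list members, which lay between 0.236 and 0.559. Spread between donors may be part of it, because the averaged hypoxia effect had 83 calls with donor as a block and 13 without. Whether the change was limited to few genes cannot be told apart from this spread, because the share of probe sets estimated to change was 4.06% without the block and 12.4% with it.

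The clock genes ARNTL (0.50 ± 0.061, adjusted p = 0.0167) and PER3 (0.49 ± 0.085, adjusted p = 0.088, and 0.0362 with donor as a block) were both higher under hypoxia. If the phase of the clock had differed at harvest, the remaining genes of its positive and negative arms (4 and 7 genes) were predicted to move apart in every within-donor comparison. The mean difference between the arms was -0.069, with a range of -0.219 to 0.026 and 2 of 6 values above 0, so the prediction was not met. None of the remaining genes was called, and their averaged changes lay between -0.06 (HLF) and 0.42 (BHLHE41). With no called gene in either arm, the test cannot decide on a phase shift, which stays open. A biological effect of oxygen on these genes was not tested separately.

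Other groupings of the same arrays were counted for each comparison. For TGF-β3 averaged over oxygen, 2 of 100 splits gave as many calls as the real 2582, so chance is excluded over splits drawn without regard to donor, and the highest other, 2725, kept all 12 arrays on their own TGF-β3 side. For averaged hypoxia 2 of 100 splits gave as many as the real 13. These splits also mix arrays with and without TGF-β3 within a group, which widens the spread, so they cannot exclude chance for hypoxia. The highest other, 53, set all arrays of donor 2 against all of donor 3 and parted those of donor 1 by oxygen. It kept 8 of 12 arrays on their own side, and thus mixes donor differences with part of the hypoxia difference. Like the real 13 it was counted without a block, so the 83 real calls with donor as a block are no match for it. Among the 4 splits that part as many donor pairs the other 3 gave 0 calls in both comparisons, but 4 are too few for a share under 0.05. For the interaction 100 of 100 splits gave at least the real 0, with a highest other of 1. A real count of 0 fixes that outcome, so it says nothing about chance. For list counts with TGF-β3 averaged over oxygen, 4 of 100 splits gave as many as the real 10, the real one included, with a highest other of 11. This share is under 0.05, but too near it over 100 random splits to exclude chance. For hypoxia averaged over TGF-β3, 3 of 100 splits gave as many (real 10, highest other 11), but the mixed TGF-β3 states leave chance open there. The exclusion for probe sets called with averaged TGF-β3 does not extend to the pairing, and the list counts do not test the pairing either. Most of those splits part 0 or 1 donor pairs, and among the 4 that part all 3 the others called up to 9 and 8 lists against the real 10, too few splits for a share under 0.05.

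For the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. For probe sets called, the real value and the highest other were 736 and 0 for TGF-β3 at 21%, 817 and 1 for TGF-β3 at 2%, 1 and 1 for hypoxia without TGF-β3, 0 and 0 for hypoxia with it, and 1002 and 0 for both against neither, and 1, 1, 2, 10 and 1 splits gave a count as large, of which the 10 follow from a real count of 0. For gene lists they were 7 and 5, 9 and 9, 10 and 7, 5 and 8, and 11 and 11 in the same order, with 1, 2, 1, 4 and 2 splits as large. The other splits called a median of 4 to 7 lists. In each of them 4 arrays stood on their own side of the comparison, and most set donors against each other. Part of the treatment and donor differences thus remained, so how many lists the preset correlation calls by itself cannot be read from them.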
